A study of Homo sapiens with 12 samples.

How the data were processed

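Libraries were made from total RNA with a stranded mRNA kit, per the labels' protocols. Reads were processed with FastQC 0.10.0 and TopHat on genome build hg19, per the submitters' processing notes, and the program that estimated abundance is not given in the sources used here. The authors deposited values per RefSeq transcript, read here as FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments). That unit was inferred from the values, since neither the file headers nor the labels name it. Each table holds 37542 transcript rows. FPKM sums are set by normalization and by short transcripts: in the hairpin table MIR4461 alone took between 13.6% and 20.9% of a library's sum.

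No read counts were analysed here, so absolute depth is unknown, but relative depth can be read from the low values. Among genes with a single transcript row and values above 0 and under 0.05 FPKM in both libraries of a pair, between 17% and 25.8% had the same ratio of values within 1%, as 1 fragment in each library would give. By that ratio a fragment was worth 1.34 times as much in E2 ShCtrl replicate 1 as in replicate 2, and 1.51 times as much in MI-2 replicate 2 as in DMSO replicate 1. Each library was therefore of somewhat different depth, and the low values of the shallower ones are less precise. The values hold no count from which an interval could be made.

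Columns were tied to samples by name. Of the columns for the hairpin experiment, 3 match no sample's labels and were not used in any step, which left 5 columns there and 4 in the MI-2 table. Vehicle-treated ShCtrl therefore had no library, and ShMEN1 with estradiol had 1. Of 8 comparisons planned, 3 were fitted: ShMEN1 against ShCtrl in estradiol, estradiol against vehicle in ShMEN1, and MI-2 against DMSO. The hairpin effect in vehicle, the estradiol effect in ShCtrl and their interaction were not analysed here, so nothing is said on whether silencing changes the response to estradiol. The averaged comparisons would reduce to those fitted, and the planned overlap of hairpin and estradiol effects was not run.

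Rows naming no gene (798 per table, 2.21% of the summed values in the hairpin table and 8.01% in the MI-2 table) were left out. Symbols that had been turned into dates (60 of those in the hairpin table) were restored by RefSeq identifier from the MI-2 table. Each gene was represented by its transcript with the highest mean, and 7124 of 22727 symbols have more than 1 transcript. Genes with a value of at least 1 FPKM in at least 2 libraries were tested on log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. A gene that passed this filter through the libraries of 1 compared group alone could only be higher in that group. The list counts and list tests include such genes. Limma 3.58.1 in R 4.3.3 was fitted per table with group means and an intensity trend in the empirical Bayes step, and p-values were adjusted by Benjamini-Hochberg at 0.05. The 3 groups of the hairpin table shared the spread, with 2 residual degrees of freedom, as did the 2 groups of the MI-2 table. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The reference annotation in hand is of another build than hg19, so no coordinates are given.

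Before the data were examined, 27 gene lists were fixed, of which a list of mitochondrially encoded genes had no member in the tables. They cover menin and its partners, the luminal and estrogen receptor program, estradiol-induced and estradiol-repressed genes, immediate-early genes, the cell cycle (G1/S and G2/M), p53 targets and CDK inhibitors, HOX genes, cholesterol and fatty acid synthesis, the integrated stress response, endoplasmic reticulum chaperones, NRF2 targets, heat shock genes, aryl hydrocarbon receptor targets, hypoxia, interferon and NF-kB genes, TGF-beta and BMP targets, markers of basal, neuroendocrine, leukocyte and fibroblast or endothelial cells, histones and ribosomal proteins. Some genes belong to more than 1 list, so results of different lists are not independent. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The estimated correlation rests on 2 residual degrees of freedom, and no list passed with it in any comparison. A list that did not pass with it is therefore not shown to be unmoved. The genes named were 9 set in advance, the 10 largest changes in each direction among called genes that separate all libraries of the groups, and up to 4 called members of each list, or 2 that did not pass where none did. For the largest changes the rule also required a mean of at least 1 FPKM in the higher group. It left out symbols of LOC, FLJ or KIAA type, chromosome open reading frames, and FAM followed by a number. Small RNA genes took all 10 of the largest falls with the hairpin and with MI-2, and 2 and 4 of the 10 largest rises, so the same rule was also applied without them, a choice made after seeing the data.

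The alternatives fixed at the same time were limma without the intensity trend, quantile normalization, no filter or a filter at 5 FPKM, a pseudocount of 0.1, a replicate block, each library left out in turn, every transcript row or the sum of transcripts, and stricter thresholds. A fit with 1 library left out has 1 residual degree of freedom. A call lost in it can reflect lost power and does not show dependence on that library. Added after seeing the data were fits without small RNA genes, rescaling to equal sums without them, the groups compared alone (planned for groups of 2 libraries, and 1 group has 1), ShMEN1 libraries of both treatments pooled, and vehicle ShMEN1 in place of estradiol ShMEN1. The fit was tested on simulated data made from the real genes' means and spreads, 5 draws per comparison with 200 genes changed. In the hairpin comparison (about 12828 genes) it recovered 56.6% of genes changed by 1 on the log2 scale and 86.2% of those changed by 2, with 3.5% of calls false. For estradiol in ShMEN1 (about 12834 genes) the shares were 49.8%, 83% and 4.6%, and for MI-2 (about 11800 genes) 76.6%, 95.2% and 3.2%. With MI-2, 3662 of 11972 genes were called, against 200 changed in a draw, so its shares do not describe that comparison. A mitotic list shifted by 0.5 was called in 5 of 5 draws in each comparison. Genes were drawn independently of one another, so neither the shares nor that call covers genes that move together.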

Results

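RNA levels were measured by sequencing in MCF-7 cells, an established line of human breast cancer cells that carry the estrogen receptor and grow in response to estradiol. The study lowered menin, the chromatin-bound protein made from MEN1, by an inducible hairpin in the first experiment and blocked it with the small molecule MI-2 in the second. In the hairpin experiment, cells carrying a hairpin against MEN1 (ShMEN1) or a control hairpin (ShCtrl) were kept for 72 h in medium stripped of hormones, with 100 ng/ml doxycycline for 72 h to switch the hairpin on. They then received 10 nM estradiol or vehicle for 45 min. In the second experiment, cells were given MI-2, labelled as 1 mM, or its solvent DMSO for 4 days. In the hairpin experiment 5 libraries could be tied to a sample by name: 2 of ShCtrl with estradiol, 2 of ShMEN1 with vehicle and 1 of ShMEN1 with estradiol. All 4 libraries of the MI-2 experiment could be tied, 2 per group. The summed values per library ran from 602183 to 671436 FPKM in the hairpin table and from 533416 to 552660 FPKM in the MI-2 table. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which can be technical.

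The first question was what loss of menin did to estradiol-treated cells. MEN1 itself (NM_130799) stood at 12.8 ± 1.2 FPKM (SD, n = 2) in ShCtrl and at 2.68 FPKM in the ShMEN1 library, a log2 difference of -1.91 (SE 0.113, adjusted p = 0.0161 by limma). The vehicle-treated ShMEN1 libraries held 3.76 ± 0.114 FPKM (SD, n = 2), so MEN1 was low in all 3 libraries labelled ShMEN1. The call of MEN1 was lost without E2 ShCtrl replicate 1 or 2 (adjusted p = 0.131 and 0.127), with a log2 difference of -1.82 or lower. Of the genes tested, 24 of 40 of DNA replication and 27 of 36 of mitosis rose, while ESR1, which encodes the estrogen receptor, and 9 of 45 genes that estradiol induces fell. Each of these counts was lower with 1 library left out, as given with its list. In total 297 of 13010 genes passed an adjusted p of 0.05, 209 higher and 88 lower in ShMEN1. Small RNA genes made up 29 of them, and the other genes split into 207 higher and 61 lower.

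**Figure D1:**
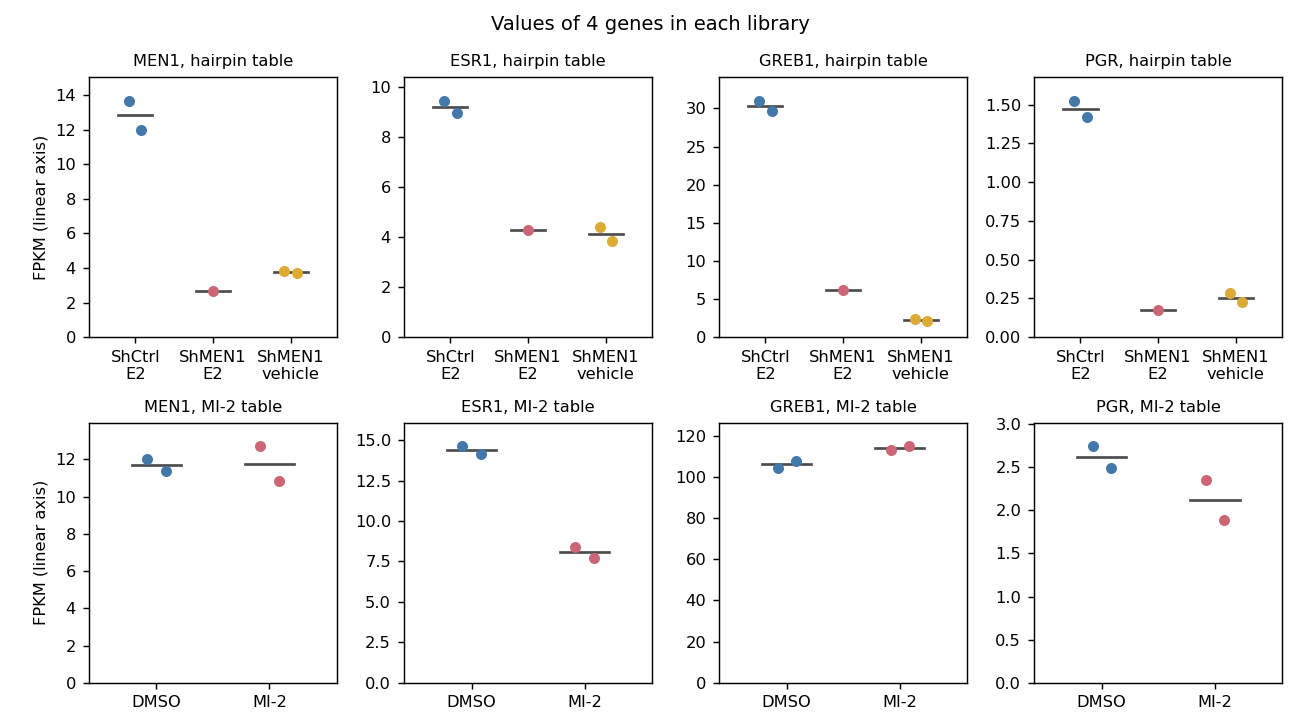
FPKM of MEN1, ESR1, GREB1 and PGR (vertical axes, linear, from 0) in each library of the hairpin table (top) and of the MI-2 table (bottom), which were normalized separately. Points are libraries and bars are group means; ESR1 was lower in ShMEN1 than in ShCtrl and lower with MI-2 than with DMSO, while MEN1 differed in the hairpin table and had means of 11.8 and 11.7 FPKM in the MI-2 table.

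Among the genes of G1/S transition and DNA replication, 24 of 40 rose and the remaining 16 did not pass. Adjusted over the list alone, 38 rose and 1 fell. TK1, a thymidine kinase that supplies nucleotides for DNA synthesis, stood at 58.5 FPKM against 13 ± 0.37 FPKM (SD, n = 2), a log2 difference of 2.08 (SE 0.0753, adjusted p = 0.0102). RRM2, a subunit of ribonucleotide reductase, rose by 2.05 on the log2 scale, GINS2, part of the replicative helicase, by 1.66 and CDC45, another helicase component, by 1.62. The mitotic list moved further, with 27 of 36 members higher over all genes and 35 of 36 adjusted over the list alone, at a median log2 difference of 1.38. In it KIF2C, a kinesin that removes tubulin from microtubule ends, rose by 1.80, AURKB, a mitotic kinase, by 1.77, CDK1, the kinase that drives entry into mitosis, by 1.76 and UBE2C, an enzyme of the anaphase-promoting complex pathway, by 1.75. Camera, which compares a list with all other genes at a preset correlation, gave adjusted p = 9e-24 for the replication list and 1.3e-31 for the mitotic list, and with an estimated correlation the adjusted p was 0.335 for both. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, gave adjusted p = 0.0235 and 0.0137 for the 2 lists. Without E2 ShCtrl replicates 1 and 2 in turn, 0 genes of either list passed in limma (37 and 33 replication genes and 35 and 35 mitotic genes at an unadjusted p under 0.05). Without Veh ShMEN1 replicates 1 and 2 in turn, 13 and 13 replication genes and 18 and 18 mitotic genes rose. The list medians were at least 0.89 and 1.34 in these 4 fits. The vehicle-treated ShMEN1 libraries lay 1.68 and 1.76 above the ShCtrl mean in the median of the mitotic list and 0.94 and 0.94 above it in that of the replication list, although they received no estradiol.

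Outside these lists the largest rises, once small RNA genes were set aside, included PKMYT1, a kinase that restrains CDK1 (1.92), HMGB2, a chromatin protein (1.85), AOX1, an aldehyde oxidase (1.79), APOBEC3B, a cytidine deaminase (1.78), and CDCA5, a cohesin regulator (1.78). CDKN2C, an inhibitor of CDK4 and CDK6, rose by 1.56 (SE 0.101) and was the called member of the list of p53 targets and CDK inhibitors, in which 25 of 26 did not pass and 2 rose adjusted over the list alone. Setting the small RNA genes aside for these names was decided after their values had been seen.

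Of 45 estradiol-induced genes tested, 9 fell, and adjusted over the list alone 19 fell and 2 rose. Camera gave adjusted p = 7.2e-16 for the list, adjusted p = 0.335 with an estimated correlation, and fry adjusted p = 0.0601. Without E2 ShCtrl replicates 1 and 2 in turn, 0 of the list passed in limma (19 and 21 at an unadjusted p under 0.05), and without Veh ShMEN1 replicates 1 and 2, 4 and 4 fell, while 18 fell with transcripts summed and 18 without small RNA genes. GREB1, a cofactor of the estrogen receptor and a widely used estradiol target, stood at 6.21 FPKM against 30.3 ± 1.01 FPKM (SD, n = 2), a log2 difference of -2.12 (SE 0.1, adjusted p = 0.0133). CA12, a carbonic anhydrase, fell by 1.09, RAPGEFL1 by 1.31 and STC2, a secreted glycoprotein, by 1.12. ESR1 stood at 4.31 FPKM against 9.21 ± 0.364 FPKM (SD, n = 2), a log2 difference of -0.94 (SE 0.112, adjusted p = 0.0438). That call was lost when any 1 of E2 ShCtrl replicates 1 and 2 and Veh ShMEN1 replicates 1 and 2 was left out, at adjusted p of 0.225, 0.207, 0.0553 and 0.057 in that order, with log2 differences between -0.98 and -0.91. PGR, the progesterone receptor, fell by 1.08. It reached 1 FPKM in the ShCtrl libraries alone, so it passed the filter through them and lies near the floor in ShMEN1. Its log2 difference ran from -2.53 to -0.91 across the alternatives. XBP1, a transcription factor of secretory cells, fell by 0.92. ESR1, PGR and XBP1 were the 3 called of 21 members of the luminal and estrogen receptor list. Adjusted over the list alone, 4 luminal genes fell. Camera called the list at the preset correlation (adjusted p = 0.000325). It was not called with an estimated correlation, at which no list passed (adjusted p = 0.335), nor by fry (adjusted p = 0.0601). Without any 1 of those 4 libraries, in the same order, 0 luminal genes passed in limma (5, 5, 10 and 10 at an unadjusted p under 0.05). FOXA1 and GATA3, transcription factors that act with the receptor, had log2 differences of 0.0047 and -0.048 and did not pass, nor did TFF1 (-0.25), MYC (-0.31) and CCND1 (-0.54, adjusted p = 0.0795). Other large falls outside small RNA genes included AGR3, a disulfide isomerase family member, at -2.35 (SE 0.14), RAMP3, a partner of calcitonin-family receptors, at -2.11, ANO7 at -1.92, NPY1R, a neuropeptide Y receptor, at -1.57, SELENBP1, a selenium-binding protein, at -1.42 and TSPAN31 at -1.20. RGS11 had -1.44, but -0.092 (adjusted p = 0.79) with transcripts summed. It passed in 8 of 16 alternatives, with adjusted p from 0.00548 to 0.79.

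Without E2 ShCtrl replicate 1, 0 genes passed in limma (1440 at an unadjusted p under 0.05, against 2375 with all libraries), without E2 ShCtrl replicate 2, 7 passed, and without Veh ShMEN1 replicates 1 and 2, 171 and 154 passed; of the called genes named and tested 0 of 40, 3 of 40, 38 of 46 and 36 of 46 kept the call in that order, and all kept their sign. Each of these fits has 1 residual degree of freedom, so the lost calls do not show that a particular library drove them. The single estradiol ShMEN1 library was assumed to vary like the other groups, and it enters both this comparison and that of estradiol with vehicle.

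The second question was what 45 min of estradiol did in cells with silenced MEN1. In these cells STC2 rose from 36.9 ± 1.21 FPKM (SD, n = 2) to 110.9 FPKM, a log2 difference of 1.56 (SE 0.0796, adjusted p = 0.0263 by limma). Of 13010 genes tested 15 passed, 6 higher and 9 lower (1295 at an unadjusted p under 0.05), and STC2 was the sole gene among them that is not a small RNA gene. Fitted without small RNA genes, a choice made after seeing the data, 11 genes passed, 9 higher and 2 lower, of which STC2 was the 1 shared with the 15. GREB1 and SLC7A5, an amino acid transporter, were among the 11 (adjusted p = 0.0408 and 0.0342). With small RNA genes in the fit, GREB1 of the estradiol-induced list had 1.16 (adjusted p = 0.0996), MYC 1.07 (adjusted p = 0.206) and CCND1 0.71 (adjusted p = 0.208), none of which passed over all genes, and SLC7A5 had 1.33 (adjusted p = 0.0923). Across the alternatives the adjusted p ran from 0.0408 to 0.297 for GREB1 and from 0.0342 to 0.267 for SLC7A5. Of the 45 estradiol-induced genes 1 rose over all genes, 19 rose adjusted over the list alone, and 41 had a positive log2 difference, with a median of 0.33. Camera gave adjusted p = 1.2e-17 for the list, and adjusted p = 0.59 with an estimated correlation. The lowest adjusted p that fry gave any list in this comparison was 0.209. ESR1 had a log2 difference of 0.05 (SE 0.112) and MEN1 of -0.37 (SE 0.113), and neither passed.

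Mitotic genes lay lower in the estradiol library, with a median of -0.30, and PLK1, a mitotic kinase, had a value of -0.42 and BUB1, a spindle checkpoint kinase, of -0.44, neither of which passed. Over all genes 0 of 36 passed in limma (17 at an unadjusted p under 0.05), adjusted over the list alone 9 fell, camera gave adjusted p = 1.2e-12, and with an estimated correlation the adjusted p was 0.59. Camera at the preset correlation also called the immediate-early list (median 0.12, adjusted p = 0.000517) and the cholesterol list (median -0.18, adjusted p = 0.000715). It called the aryl hydrocarbon receptor list (median 0.24, adjusted p = 0.00584) and the TGF-beta and BMP list (median 0.13, adjusted p = 0.0126) too. With an estimated correlation, at which no list passed, camera gave these lists adjusted p = 0.59, 0.59, 0.684 and 0.59. Over all genes 0 of their 27, 24, 10 and 15 members passed in limma, 10, 4, 4 and 3 had an unadjusted p under 0.05, and 2, 0, 1 and 0 rose adjusted over the list alone.

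The call of STC2 was lost when any 1 of E2 ShCtrl replicates 1 and 2 and Veh ShMEN1 replicates 1 and 2 was left out, at adjusted p of 0.0905, 0.0828, 0.0796 and 0.0983 in that order, with log2 differences of at least 1.53. Without E2 ShCtrl replicates 1 and 2, which enter this comparison through the estimate of the spread and the filter on low values, 24 and 31 genes passed.

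The third question was how cells responded to 4 days of MI-2. MEN1 stood at 11.8 ± 1.33 FPKM (SD, n = 2) with MI-2 and at 11.7 ± 0.465 FPKM (SD, n = 2) with DMSO, a log2 difference of 0.0057 (SE 0.0963, adjusted p = 0.97). ESR1 fell from 14.4 ± 0.315 to 8.06 ± 0.488 FPKM (SD, n = 2 each), a log2 difference of -0.77 (SE 0.0764, adjusted p = 0.00446). Among the genes tested, 14 of 21 NRF2 targets (8 without MI-2 replicate 2), 15 of 25 immediate-early genes and 7 of 13 fatty acid synthesis genes rose, while 13 of 40 replication genes (between 3 and 7 with 1 library left out), 10 of 24 cholesterol genes and 6 of 22 histone genes fell. Of 11972 genes tested 3662 passed, 2026 higher and 1636 lower with MI-2; after rescaling the libraries to equal sums without small RNA genes the split was 1705 higher and 2226 lower.

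Among the largest changes outside small RNA genes, GDF15, a secreted stress-induced cytokine, rose from 28.5 ± 0.108 to 227.1 ± 19.6 FPKM (SD, n = 2 each), a log2 difference of 2.95 (SE 0.0861, adjusted p = 0.000283). ABCG1, a sterol exporter, rose by 2.86, AQP3, a water and glycerol channel, by 2.16, ASPH by 1.92 (0.97 with transcripts summed) and TMEM45B by 1.82. KRT81 and KRT86 rose by 2.66 and 1.99, but these keratins are near-identical in sequence and their values are uncertain where reads could be shared. Outside small RNA genes the largest falls by the naming rule were of MSMB, a secreted protein of glandular epithelia, at -1.86, SEPP1, a selenium transport protein, at -1.80, SHH, a developmental signal, at -1.73, SOX2, a stem cell transcription factor, at -1.68, SULF1 at -1.56, ADAMTS19 at -1.54, CAV1, the caveolar coat protein, at -1.53, IFI6, an interferon-induced gene, at -1.53 and SOCS2, a feedback inhibitor of cytokine signals, at -1.52. SEPP1 reached 1 FPKM in the DMSO libraries alone, and its log2 difference ran from -2.61 to -1.775 across the alternatives. The call of IFI6 was lost without MI-2 replicate 2 (adjusted p = 0.0706).

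Of 21 targets of NRF2, the regulator of antioxidant genes, 14 rose and 1 fell over all genes, and 15 rose and 1 fell adjusted over the list alone. ABCC3, a conjugate exporter, rose by 2.48 (SE 0.114), OSGIN1 by 1.74, AKR1B10, an aldo-keto reductase, by 1.12 and TXNRD1, a thioredoxin reductase, by 0.90. AKR1B10 reached 1 FPKM in the MI-2 libraries alone, and its log2 difference ran from 1.055 to 3.04 across the alternatives. In the immediate-early list 15 of 25 rose, and 17 adjusted over the list alone, among them DUSP5, a phosphatase of ERK, by 1.77, EGR1 by 1.70 and CTGF by 1.03. With either MI-2 library left out, 23 of the 25 immediate-early and 20 of the 21 NRF2 genes passed the filter on low values. The others reached 1 FPKM in the MI-2 libraries alone, so they could only be higher with MI-2. Endoplasmic reticulum chaperones and unfolded protein response genes included 11 of 20 that rose, the same count adjusted over the list alone, with CALR at 0.71 and HYOU1 at 0.61. Of 13 fatty acid synthesis genes 7 rose, and 8 adjusted over the list alone, with SCD, a desaturase, at 1.12 and FASN, the fatty acid synthase, at 1.11. By contrast 10 of 24 cholesterol genes fell, the same count adjusted over the list alone, including ACAT2 at -0.81, IDI1 at -0.81 and HMGCS1 at -0.74. Of 7 aryl hydrocarbon receptor targets 5 rose, and 6 adjusted over the list alone, with ALDH1A3 at 1.41 and CYP1B1 at 0.96. In the TGF-beta and BMP list 9 rose and 1 fell of 15, the same counts adjusted over the list alone, with ID1 at 0.91. Without MI-2 replicate 2, 8 NRF2, 5 endoplasmic reticulum and 5 TGF-beta genes rose.

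Replication genes fell in 13 of 40 cases and rose in 1, with the same counts adjusted over the list alone, led by CCNE2 at -0.80 and DHFR at -0.69, while CCND1, the D-type cyclin that estradiol induces, rose by 0.82 (SE 0.0734). Of 36 mitotic genes 8 rose and 2 fell, the same counts adjusted over the list alone, and camera did not call that list (adjusted p = 0.162). Without MI-2 replicates 1 and 2 and DMSO replicates 1 and 2 in turn, 3, 7, 5 and 6 replication genes fell, and 1 mitotic gene rose without MI-2 replicate 2 and 4 without DMSO replicate 2. Replication-dependent histones, a family of near-identical genes whose values are uncertain, fell in 6 of 22 cases and rose in 1, the same counts adjusted over the list alone, with HIST1H4H at -1.39. Estradiol-induced genes went both ways, 16 up and 10 down of 48, with 18 up and 10 down adjusted over the list alone: FHL2 at 1.82 and GAB2 at 1.32 rose, PDZK1 at -1.51 and CXCL12 at -1.26 fell, and TFF1 rose by 0.61, a call lost without DMSO replicate 2 (adjusted p = 0.0539). GREB1 (0.10), PGR (-0.22), MYC (-0.14), FOXA1 (0.22) and GATA3 (-0.24) did not pass.

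**Figure D2:**
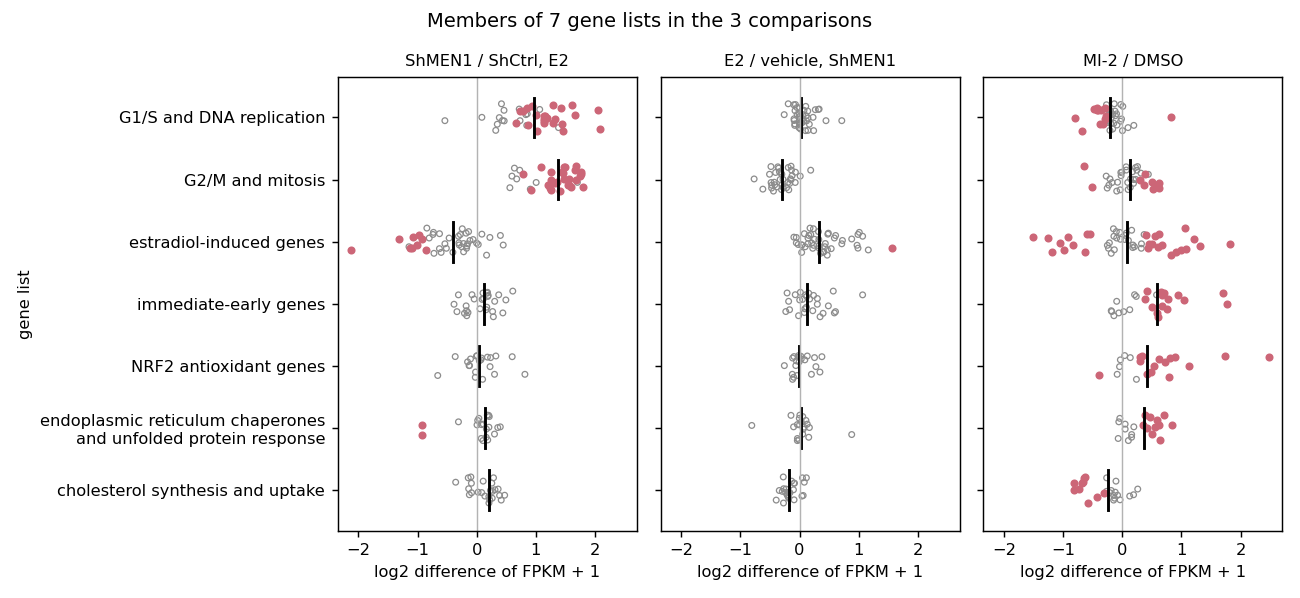
Log2 differences of FPKM + 1 (horizontal axis) of the tested members of 7 gene lists (rows) in the 3 comparisons (panels). Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians; the G2/M list has medians of 1.38, -0.30 and 0.14 from left to right.

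Camera called 9 lists in this comparison at the preset correlation, with adjusted p from 5.8e-05 (NRF2 and immediate-early lists) to 0.0322 (TGF-beta and BMP list). Some of these lists share members, so their calls are not independent. JUNB and CTGF are in both the immediate-early and TGF-beta lists, and ME1 is in both the NRF2 and fatty acid lists. With an estimated correlation camera gave adjusted p = 0.579 for the NRF2, immediate-early, fatty acid, aryl hydrocarbon receptor, TGF-beta and histone lists. It gave 0.59 for the replication, cholesterol and endoplasmic reticulum lists. No list passed at that setting in any comparison, so it cannot tell these lists from others. Fry called 12 lists, of which 7 were among those 9. The others were the luminal (adjusted p = 0.0184), p53 (0.0209), HOX (0.0376), NF-kB (0.0103) and basal (0.0184) lists. It did not call the replication (0.104) and cholesterol (0.0795) lists. Fewer genes than 3662 passed with 1 library left out. Those fits have 1 residual degree of freedom and a group of 1 library, so the drop does not show dependence on a particular library. All called genes named and tested kept their sign in them.

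The labels join silencing and inhibition under a single aim, so the genes called in the estradiol-treated hairpin comparison were set against those called with MI-2. The tables were normalized separately and share no library. Of 11733 genes tested in both, 46 were called in the same direction and 43 in opposite directions. That order turned at an adjusted p of 0.1 (124 and 128), with transcripts summed (118 and 123) and after rescaling (44 and 53). Of the genes called in both, 16 genes fell in both, where independent lists would share 8.8 (Fisher's exact test, two-sided, p = 0.0165, adjusted p = 0.0658 over the 4 pairs of directions), which did not pass. In 8 of 10 alternatives this excess passed, with adjusted p from 0.000142 to 1 across them. The lowest came with the ShMEN1 libraries pooled (62 genes against 37.2), a fit that also compares treatments. Fisher's test treats genes as independent, and genes that move together were not accounted for. ESR1, AGR3, NPY1R and RAMP3 were among the 16, as were CXCL12 and RET, a receptor tyrosine kinase, the last chosen after its values were seen. A further 30 genes rose in both against 33.1 for independent lists, and 34 rose with the hairpin and fell with MI-2 against 27.2, including RRM2 and DHFR. In 9 cases a gene fell with the hairpin and rose with MI-2, against 10.8. The adjusted p of these 3 was 0.737, 0.35 and 0.737 in that order. The second of these passed in 0 of 10 alternatives (Fisher's exact test, lowest adjusted p = 0.058, highest 1). The others passed in 1 alternative each, with the ShMEN1 libraries pooled, and had a highest adjusted p of 1. There 151 genes rose in both against 125.1 (adjusted p = 0.0197) and 60 fell with the hairpin and rose with MI-2 against 45.4 (adjusted p = 0.028). The hairpin side of that fit also compares treatments, since it sets vehicle ShMEN1 libraries against estradiol-treated ShCtrl. Across the 11733 genes, which are not independent replicates, the log2 differences had a Pearson r of 0.021 and a Spearman rho of 0.025.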

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

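The fits without small RNA genes, the rescaled fits, the groups compared alone, the pooled ShMEN1 libraries and the vehicle ShMEN1 libraries were chosen after seeing the data. Except where a value or the construction of the fit shows it, the cause of a change was not tested. The count of 297 genes for ShMEN1 against ShCtrl in estradiol was 5 at an adjusted p of 0.01 and 192 with a log2 change of at least 1, both subsets by construction. It was 55 without a filter on low values, which tests more genes, and 45 over every transcript row, which tests more rows. It was 565 with transcripts summed and 592 without small RNA genes. With ShMEN1 libraries pooled, which adds libraries, it was 1100. It was 1612 with vehicle ShMEN1 libraries in place of the estradiol library. The pooled and the vehicle fits also compare treatments, since they set vehicle ShMEN1 libraries against estradiol-treated ShCtrl. Leaving out 1 library gave from 0 to 171 genes, with fewer libraries to estimate the spread. The counts of 24 replication and 27 mitotic genes higher and 9 estradiol-induced genes lower became 3, 7 and 1 without the filter, 4, 8 and 1 over every transcript row, and 1, 0 and 1 with a replicate block (36, 35 and 25 at an unadjusted p under 0.05 in limma). There were 15 replication genes with quantile normalization, and 17 estradiol-induced genes with ShMEN1 pooled and 29 with vehicle ShMEN1. For estradiol against vehicle in ShMEN1 the count of 15 was 5 at an adjusted p of 0.01, 26 without the filter, 27 with a pseudocount of 0.1, 5 over every transcript row, 26 with transcripts summed 23 with the groups compared alone and 11 without small RNA genes, and from 11 to 31 with 1 library left out. For MI-2 against DMSO the count of 3662 was 1032 at an adjusted p of 0.01 and 241 with a log2 change of at least 1, and from 1833 to 2658 with 1 library left out, and its 13 replication genes lower were 6 without the filter and 7 over every transcript row. The 46 genes called in the same direction by the hairpin and by MI-2 were 124 at an adjusted p of 0.1, 3 without the filter, 118 with transcripts summed, 139 without small RNA genes and 213 with ShMEN1 libraries pooled, where 128, 2, 123, 127 and 179 were called in opposite directions.

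Replicate numbers are shared by groups, and a replicate block gave 29 genes for the hairpin, 24 for estradiol, 3704 for MI-2 and 1 for the overlap. Deviations of libraries with the same number correlated at 0.009 in the hairpin table and 0.134 in the MI-2 table (0 and 0.193 without small RNA genes), from 1 pair of groups each, and no label says what a number marks, so the numbers were not taken to pair the libraries.

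Some named genes changed sign, none of them past the threshold in the changed fit. For the hairpin, FOXA1 had -0.0455 with quantile normalization, -0.0327 with the block, -0.0328 after rescaling, -0.0302 with pooled ShMEN1, -0.0476 with vehicle ShMEN1, and from -0.0101 (without E2 ShCtrl replicate 1) to 0.0195 (without replicate 2) with 1 library left out. GATA3 had 0.0186 with pooled and 0.0518 with vehicle ShMEN1, LYZ 0.0088 with vehicle ShMEN1 and from -0.264 to 0.027 with a library left out (the latter without E2 ShCtrl replicate 2), and MIR4519 and MIR4700, which were called, 0.70 and 0.64 with vehicle ShMEN1. For estradiol, ESR1 had -0.0080 with the block, and without Veh ShMEN1 replicates 2 and 1 ESR1 had -0.0306 and 0.133, FOXA1 -0.0372 and 0.142 and HBA1 0.275 and -0.0044, PGR 0.15 with quantile normalization and 0.18 with transcripts summed, PSIP1 -0.12 and SYVN1 0.16 with transcripts summed. With MI-2, MEN1 had -0.0314 with quantile normalization, -0.0421 after rescaling, -0.0318 without DMSO replicate 2, and from -0.101 to 0.112 without MI2 replicates 1 and 2. ESR1 kept its sign in all 17 alternatives of the hairpin comparison and its call in 9 of them (adjusted p from 0.00517 to 0.225), and in MI-2 it kept its call in all 14.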

Other observations

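All tests of explanations reported in this part were chosen after the results they bear on had been seen. Other lists in the hairpin comparison held few calls. ADM, a vasodilator peptide, and EGLN3, an oxygen sensor, rose by 1.21 and 0.89 in the hypoxia and glycolysis list of 25 tested while SLC2A1, a glucose transporter, fell by 1.05, and adjusted over the list alone 3 rose and 2 fell. LUM, which encodes an extracellular matrix protein, rose by 1.38 from 0.309 ± 0.0591 FPKM (SD, n = 2) to 2.40 FPKM (0.91 with vehicle ShMEN1 in place of the estradiol library), 1 of 3 fibroblast and endothelial markers tested and 1 adjusted over the list alone. In the interferon list 0 of 23 genes passed in limma (9 at an unadjusted p under 0.05) and 4 rose adjusted over the list alone. Among them ISG15 had 0.58 (limma adjusted p = 0.124 over all genes). Camera called the list (adjusted p = 0.0459), but not with an estimated correlation (adjusted p = 0.894), at which no list passed. The endoplasmic reticulum list held 2 genes called lower, XBP1 and SYVN1 (-0.93), and the integrated stress list 1, STC2, with the same counts adjusted over the list alone. SYVN1 had -0.0126 (adjusted p = 0.944) with transcripts summed and passed in 7 of 17 alternatives, with adjusted p from 0.00638 to 0.944. The calls named in this paragraph were lost without E2 ShCtrl replicate 1 or 2 (adjusted p from 0.128 to 0.202). Those of LUM, XBP1 and SYVN1 were also lost without Veh ShMEN1 replicate 1 or 2, and that of EGLN3 without Veh ShMEN1 replicate 2 (adjusted p from 0.0501 to 0.0633).

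With MI-2, p53 targets and CDK inhibitors included 8 of 25 that rose and 4 that fell (9 and 4 adjusted over the list alone), led by PLK3 at 0.86 and CDKN1A, the p21 inhibitor, at 0.85. Of 25 integrated stress genes 8 rose and 1 fell, the same counts adjusted over the list alone, with DDIT3 at 1.05 (0.67 with transcripts summed) and ATF5 at -1.38, and 5 of 17 interferon genes fell (4 adjusted over the list alone). CD68, a lysosomal protein listed as a leukocyte marker, rose by 1.76 and ENO2, listed as a neuroendocrine marker, by 1.06, each the single tested member of its list. CD68 reached 1 FPKM in the MI-2 libraries alone, so it passed the filter through them. Its log2 difference ran from 1.73 to 2.55 across the alternatives. CD44 rose by 1.29 and EGFR by 0.65 among basal and mesenchymal markers, where 2 of 6 rose and 1 fell (4 and 1 adjusted over the list alone). Of 8 NF-kB genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), and of 13 HOX genes 2 rose and 2 fell, the same counts adjusted over the list alone. With either MI-2 library left out 6 of the 8 NF-kB genes passed the filter on low values. The others passed it through the MI-2 libraries alone and could only be higher. With either DMSO library left out 12 of the 13 HOX genes passed it, so the remaining gene could only be lower. In the estradiol-repressed list 8 rose and 5 fell of 19, in the hypoxia list 5 and 6 of 25 and in the luminal list 4 and 7 of 20, against 8 and 6, 6 and 8, and 5 and 9 adjusted over the list alone. The medians of the first 2 of these were -0.07 and -0.23 and their means 0.05 and 0.01, of opposite sign. Among 13 heat shock genes 2 rose and 1 fell, and among 11 genes of menin and its partners JUND rose by 0.39 and PSIP1 fell by 0.47 (-0.28 with transcripts summed), while adjusted over the list alone 0 passed in either list in limma, with 5 members of each at an unadjusted p under 0.05. In the heat shock list the calls of BAG3 and DNAJB1 were lost without any 1 of the 4 libraries, and that of HSPB1 without MI-2 replicates 1 and 2 and DMSO replicate 2, each left out alone (adjusted p from 0.0502 to 0.18). The call of HOXB9 was lost without any 1 of the 4 libraries and those of HOXA13 and MEIS1 without MI-2 replicates 1 and 2 and DMSO replicate 2 (adjusted p from 0.0519 to 0.13). With MI-2 replicates 1 and 2 and DMSO replicates 1 and 2 left out in turn, 7, 5, 6 and 7 p53 targets rose and 2, 2, 3 and 1 fell, 4, 3, 4 and 6 integrated stress genes rose and 4, 1, 3 and 3 interferon genes fell. In that order 2, 2, 2 and 4 NF-kB genes rose and 1, 1, 2 and 1 fell, 3, 4, 4 and 3 estradiol-repressed genes fell, 3, 3, 5 and 4 hypoxia genes rose and at most 3 fell, and 3, 3, 3 and 1 luminal genes rose. The call of JUND was lost without MI-2 replicates 1 and 2 and DMSO replicate 2, each left out alone (adjusted p of 0.107, 0.0938 and 0.164), and that of PSIP1 without MI-2 replicate 1 and DMSO replicates 1 and 2 (0.082, 0.0582 and 0.111). Camera called none of the lists of this paragraph that had at least 5 members. Fry, which does not compare a list with other genes, called the NF-kB, luminal, basal, p53 and HOX lists (adjusted p of 0.0103, 0.0184, 0.0184, 0.0209 and 0.0376), with medians of 0.42, -0.12, 0.46, 0.11 and -0.06. Ribosomal protein genes held 0 calls of 39 in limma in each comparison, over all genes and adjusted over the list alone, with 0, 0 and 3 at an unadjusted p under 0.05 and medians of 0.01, -0.06 and 0.07.

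The rise of the cell-cycle lists in ShMEN1 was weighed against chance deviations of libraries and against scaling. Both vehicle ShMEN1 libraries, which had no estradiol, were also above the ShCtrl mean, by medians of 1.266 and 1.344 over the 2 lists, which argues against a deviation of the single estradiol ShMEN1 library, and against each ShCtrl library alone the median was 1.15 and 1.196. After rescaling it was 1.131 against 1.168, so short transcripts taking a share of the library do not account for it. A rise of that size was not seen with MI-2, where the 90th percentile of the same genes was 0.377 and the median -0.096. The lists went opposite ways there, with medians of 0.14 for mitosis and -0.21 for replication. Of the mitotic genes 8 of 36 were higher, against 2026 of 11972 over all genes tested. Camera did not call the mitotic list (adjusted p = 0.162). Of the 30 genes called higher in both comparisons, against 33.1 for independent lists, BUB1, CDC20, CENPA, PLK1, PTTG1 and UBE2C were mitotic. A smaller rise of the mitotic list as a whole in both was not shown, nor is it excluded. A growth difference between the cells carrying each hairpin, or an effect of the hairpin on other genes, may still account for the rise in ShMEN1. The labels name 1 hairpin against MEN1, and neither account was tested.

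Small RNA genes took all 10 of the largest falls with the hairpin and with MI-2. SNORD47 was listed at 0 in both MI-2 libraries and at 1081 and 1372 FPKM in the DMSO libraries, and MIR4690 at 0 in all 3 ShMEN1 libraries and at 233.8 and 350.8 FPKM in ShCtrl. Over all small RNA genes tested, differences of at least 2 on the log2 scale were as common between replicates as between groups. The shares were 28.5% against 28.7% in the hairpin table (E2 ShCtrl and vehicle ShMEN1) and 25.4% against 24.6% in the MI-2 table, ratios of 0.992 and 1.036. That goes with noisy abundance estimates of very short transcripts. The shares were not taken over the called genes, so they do not settle whether noise made those changes. Other genes showed such replicate differences 0.001 times as often, which argues against noise common to every gene. No biological explanation was tested.

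ESR1 was lower in both experiments, although its call with the hairpin was lost when any 1 of E2 ShCtrl replicates 1 and 2 and Veh ShMEN1 replicates 1 and 2 was left out (adjusted p of 0.225, 0.207, 0.0553 and 0.057). The sum over all ESR1 transcripts differed by -0.734 with MI-2 and by -0.94 with the hairpin, which argues against a shift of reads between transcripts, and after rescaling the values were -0.813 and -0.976, which argues against scaling. Whether loss of menin accounts for the lower ESR1 RNA in either experiment was not tested. The time and the agent differ between the experiments. Hormone-stripped medium is recorded for the hairpin experiment alone, so the medium may differ too. MEN1 RNA, lower with the hairpin, had a log2 difference of 0.0057 with MI-2.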
